A study of Mus musculus with 2 samples.

How the data were processed

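MicroRNA sequencing was run on total RNA from limbs of mouse embryos at embryonic day 13.5, with 2 biological replicates in 1 group, and per the labels the RNA was of a short size range. For each library the authors deposited a table of whole-number read counts for 1973 miRNA genes, with 3 count columns (either strand, sense and antisense) after 4 leading lines for reads in no gene. The meaning of these columns was taken from their layout, which matches that of STAR gene counts: no header names them, and in all 1973 genes the first column equals the sum of the others. Per the labels the build is mm10, and the text deposited with the counts names GENCODE M4 as the annotation. The aligner, the counting program and their settings are not given in the sources used here. The counts are per hairpin gene, so the arms of a hairpin are not told apart, and reads that map to several places enter no gene.

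Replicate 1 held 12407140 reads and replicate 2 held 12657170. Lines that name no gene stayed out of library sizes and tests: unmapped reads were 17.2% and 18.6% of all reads, multimapping reads 30.8% and 29.5%, and uniquely mapped reads on the sense strand of no gene 4.24% and 4.48%. No read was listed as ambiguous. Sense counts in genes were 5927321 and 6003632, or 47.8% and 47.4% of all reads, and CPM values use these totals. Column totals were equal across the 3 columns of a library, so all its reads are accounted for. A count of 0 was given a limit of 3 counts, 0.506 CPM in replicate 1 and 0.4997 CPM in replicate 2. No molecular identifiers were recorded in the sources used here, so intervals and limits cover counting error only.

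Gene symbols, coordinates, host genes and hairpin sequences came from GENCODE M21 on GRCm38, the same build as mm10 with a newer annotation release. Identifiers matched without their version for 1894 of the 1973 genes. The other 79 kept no symbol, and 3 of them had any sense count, 6 counts in total. Host genes were taken from annotation on the same strand. A hairpin was assigned to an exon where it overlapped any annotated exon of the host, without a test of whether it lay wholly inside. Genes were searched for identical stretches of 18 or more and 22 or more hairpin bases shared with another annotated miRNA gene. Copies outside the annotated miRNA genes were not searched.

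The lists (19, with 205 symbols, 180 of them counted), the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 25 genes with the highest mean CPM, up to 4 detected members of each list with the highest mean CPM, and the 10 genes with the largest ratio between libraries among those past the threshold, 81 genes in all. Of the list symbols without values, 18 are in the annotation but not counted under their own gene here, and 7 are not in the annotation by that name.

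A gene was called detected with at least 10 sense counts in each library. Correlations used log2(CPM + 1) over genes with at least 10 counts in at least 1 library. The biological coefficient of variation was the square root of the common dispersion from edgeR with TMM factors and an intercept-only design. Genes were compared between libraries with a two-sided exact binomial test, Benjamini-Hochberg adjusted at 0.05, with an absolute log2 ratio of at least 1 after adding 0.5 counts. List medians were set against 10000 random lists, and next neighbours on the same strand within 10 kb against shuffled partners with 100000 resamples. For hairpin GC content, each epithelial gene was set against the 20 genes of nearest GC among 180 genes outside the list with at least 100 CPM, with 2000 bootstrap draws of those genes, a test chosen after the data were seen. Values are given as mean ± SD over the 2 libraries. Because there is 1 group, no comparison between conditions was made, and ratios of lists carry no test.

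The methods were tested on simulated data drawn from the means and sizes of these libraries. Coefficients of variation of 0.05, 0.1 and 0.3 were estimated as 0.0537, 0.0998 and 0.304. The binomial test was run on counts with counting error only, without the minimum ratio, and with library sizes taken from unchanged genes. It recovered 78% of 50 genes changed 2-fold, 92% at 4-fold, 66% at 0.5-fold and 76% at 0.25-fold. Among the 448 genes tested, 6 unchanged genes passed. The libraries here spread beyond counting error and calls needed the minimum ratio, so these rates need not hold for the calls reported.

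Alternatives tried were other count minimums and pseudocounts, both strands counted together, other denominators, DESeq2 size factors and dispersions, other neighbour distances, list medians in place of sums, lists without genes that share sequence, and each library alone. Those added after the data had been seen left out genes sharing 22 or more bases or the most abundant member of each list, took 1 neighbour pair per cluster, dropped the minimum ratio, or used both strands for the coefficient of variation. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Text files deposited beside the counts hold no measurements and were used only for their description.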

Results

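MicroRNA libraries were made from total RNA of limbs of mouse embryos at embryonic day 13.5, when the limb holds condensing cartilage, forming muscle, vessels, blood, ingrowing nerve and a covering ectoderm. The embryos were of the B6NCrl strain, with both sexes mixed. The series holds 1 group with 2 biological replicates, taken from separate tissue samples that carry the same donor label, and it contains no treated, mutant or second-tissue group. The values below therefore describe the miRNA genes of this tissue, set against each other and against the spread of the 2 libraries. Replicate 1 held 12407140 reads, of which 5927321 were counted on the sense strand of a miRNA gene. Replicate 2 held 12657170 reads, of which 6003632 were so counted. Levels are given as CPM, sense counts scaled to the gene-assigned total of the library. A count of 0 allows up to 0.506 CPM in replicate 1 and 0.4997 CPM in replicate 2. These limits cover counting error only.

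Among miRNA genes as counted here, from uniquely mapped sense reads, 2 had the highest means. These were Mir196b, at 75238 ± 6154 CPM (SD, n = 2), and Mir335, at 75047 ± 2156 CPM (SD, n = 2). Mir196b, a Hox cluster miRNA gene, lies on chromosome 6 at 52230081 to 52230165 (mm10), overlapping an annotated exon of Hoxa9. Mir335 lies on the same chromosome at 30741299 to 30741396, in an intron of the imprinted gene Mest. Their order was not resolved: Mir196b was higher in replicate 1 (79590 against 73522 CPM) and Mir335 in replicate 2 (76572 against 70886 CPM). Next by mean came Mir322 on the X chromosome at 69568 ± 6003 CPM, Mir99a at 62771 ± 673 CPM and the cartilage miRNA gene Mir140 at 46627 ± 99.8 CPM. In replicate 2 Mir322, at 73813 CPM, lay above Mir196b, so its place below Mir196b was not resolved either.

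Mirlet7g, in an intron of Wdr82, reached 40430 ± 1594 CPM, and Mirlet7i 31984 ± 3757 CPM. Mir23b, Mir130a and Mir17 lay at 34952 ± 1513, 32213 ± 1679 and 30533 ± 4775 CPM. Mir214, overlapping an annotated exon of Dnm3os, followed at 28501 ± 837 CPM. Further down, Mir99b, Mir26b and Mir126a lay at 25670, 24862 and 20233 CPM, and Mir100, Mir23a and Mir30e at 17236, 15886 and 15602 CPM. The 10 most abundant genes held 49.9% ± 0.5 (SD, n = 2) of the sense counts. The first gene was 78.0-fold above the 100th. None of the 25 most abundant genes shares 22 or more identical hairpin bases with another annotated miRNA gene, while 7 share 18 to 21 bases. The counting favors genes without copies, as reads mapping to several places enter no gene. The 869 genes sharing 22 or more bases held 2.66% of counts, so genes with copies may rank too low.

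**Figure D1:**
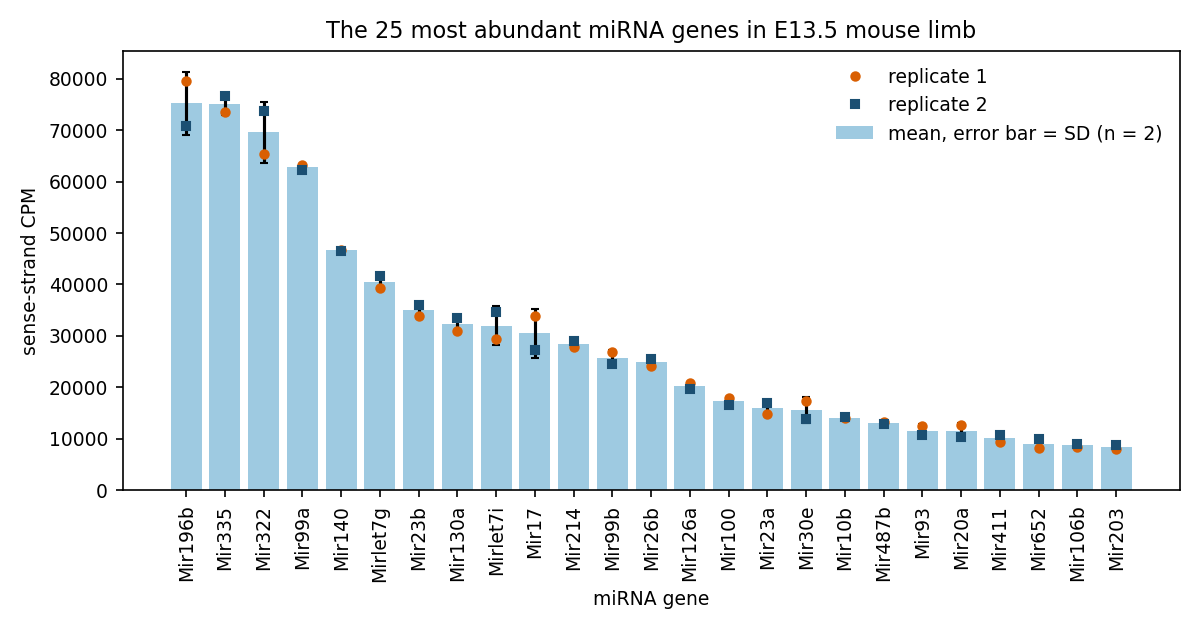
Sense-strand CPM for the 25 most abundant miRNA genes of the limb, with bars for the mean, error bars for the SD (n = 2) and points for each replicate. Mir196b and Mir335 overlap at about the same height, and Mir140 shows a narrow spread, 46627 ± 99.8 CPM.

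Of 1973 miRNA genes counted, 372 (18.9%) had at least 10 counts in each library. A further share was seen at lower depth, with 570 genes reaching at least 1 count in each library. No count was found in either library for 1259 genes, which at this depth is a limit on uniquely mapped reads and not evidence of absence. Genes that share 22 or more identical bases with another miRNA gene numbered 869, and 66 of them were detected. Their values are uncertain, because reads mapping to several places enter no gene, and such reads made up 30.8% and 29.5% of all reads in replicates 1 and 2.

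Hox cluster genes were prominent in the limb profile. The 4 Hox cluster genes of the mir-196 and mir-615 kind held 7.78% ± 0.63 (SD, n = 2) of counts, of which Mir196b made up 96.7%. Mir615 and Mir196a-2, both in introns of Hoxc5, lay at 1573 ± 58.8 and 964 ± 122 CPM, and Mir196a-1 at 21.7 ± 1.3 CPM. Mir196a-1 and Mir196a-2 share 22 bases, so their values are uncertain. The Hox cluster genes Mir10b (14101 ± 232 CPM, in introns of Hoxd3 and Hoxd4) and Mir10a (5824 ± 389 CPM) together held 1.99% ± 0.02. Counts of the Mir10a and Mir10b pair were 3.90-fold below those of the other Hox list, a log2 ratio of -1.96 ± 0.11 (SD, n = 2). That direction belongs to Mir196b: without the most abundant member of each list the log2 ratio was 1.19, and between list medians it was 2.88. Undercounting of Mir196a-1 and Mir196a-2 could raise both of these values, as Mir10a and Mir10b share no such stretch.

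The fixed list for the imprinted Dlk1-Dio3 region on chromosome 12 held 7.42% ± 0.13 of counts, with 41 of its 44 counted members detected. The list does not cover the whole region: Mir1197, for example, lies there outside it. Its most abundant counted members were Mir487b at 12961 ± 283 CPM, Mir411 at 10056 ± 883 CPM, Mir127 at 8253 ± 224 CPM and Mir431 at 6004 ± 391 CPM. The listed Mir409, Mir376a, Mir299a and Mir380 are not counted under their own genes here, so share and order leave them out. Antisense reads over the genes opposite them reached 8061, 3829, 2029 and 1654 CPM. Other imprinted genes held 8.49% ± 0.20, with 5 of 5 detected, and Mir335 made up 88.4% of that. Mir296, Mir483 and Mir298 lay at 5009 ± 114, 2758 ± 181 and 1897 ± 184 CPM, Mir483 in an intron of Igf2. The list of Sfmbt2 intronic genes, from a repeat-derived imprinted cluster, held 0.411% ± 0.008 with 5 of 21 counted members detected. The whole cluster, 107 genes with 10 detected, held 0.485% ± 0.017. Of the list members 20 share 22 or more bases with another gene, so Mir467e (1450 ± 39.2 CPM) and Mir467d (1358 ± 35.8 CPM) are uncertain. Without genes sharing 18 or more bases the list held 6.29e-05%.

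The differentiation-associated let-7 family held 8.48% ± 0.67 (SD, n = 2) of counts, and 10 of 10 counted members were detected. Mirlet7e and Mirlet7f-1 are not counted under their own genes here. Antisense reads over the genes opposite them reached 5415 and 50.1 CPM. Mirlet7d and Mir98 lay at 6041 ± 869 and 3145 ± 373 CPM, behind Mirlet7g and Mirlet7i. Of the 10 counted members 5 share 22 or more bases with another gene and may be undercounted. The let-7 share may therefore be too low, and the order within the family is uncertain. The pluripotency list held 0.0142% ± 0.0004, with 6 of 12 members detected, led by Mir302a at 51.7 ± 4.4 CPM and Mir302d at 41.0 ± 5.5 CPM. The log2 ratio of let-7 over pluripotency counts was 9.22 ± 0.15 (SD, n = 2). The proliferation-associated Mir17 cluster and its paralogs held 7.20% ± 0.73, with 15 of 15 members detected. Among them, Mir93 overlaps an annotated exon of Mcm7 and Mir106b lies in an intron of it. The X-linked Mir322 and Mir503 list held 8.10% ± 0.56, with 5 of 5 detected. Without genes that share 18 or more bases, which removes Mirlet7g and Mirlet7i, let-7 held 1.15% and the log2 ratio of let-7 over pluripotency was 7.31.

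Among lists for the tissues of the limb, mesenchyme and bone held the most counts, 6.88% ± 0.19 (SD, n = 2), with 9 of 9 members detected. Mir23b made up 50.8% of that, and Mir214, Mir27b and Mir199b lay at 28501 ± 837, 2908 ± 140 and 1995 ± 572 CPM. Mir199b shares 28 bases with Mir199a-1 and is uncertain. Without genes sharing 18 or more bases, Mir23b among them, cartilage led instead, at 6.09% of the remaining counts against 3.58% for mesenchyme and bone. Cartilage held 4.86% ± 0.006, nearly all in Mir140, with Mir455 of Col27a1 at 2020 ± 40.0 CPM. Mir140 lies on chromosome 8 at 107551244 to 107551313 and overlaps an annotated exon of Wwp2. Epithelium held 2.69% ± 0.23, with 10 of 10 members detected, among them Mir203 (8388 ± 589 CPM), Mir205 (6918 ± 918 CPM), Mir429 (3730 ± 498 CPM) and Mir183 (2154 ± 176 CPM). The log2 ratio of mesenchyme and bone over epithelium was 1.36 ± 0.08 (SD, n = 2). It was 0.091 without genes sharing 18 or more bases, 1.31 without those sharing 22 or more, and -2.57 between list medians. Its direction thus depended on how the members were weighed. Of the mesenchyme and bone members 5 of 9 share 22 or more bases with another gene, against 0 of 10 epithelial members. Those 5 may be undercounted, which would lower the mesenchyme and bone median, so the reversal between medians does not settle the direction.

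Skeletal muscle genes held 0.410% ± 0.015 (SD, n = 2) of counts, and the muscle miRNA gene Mir206 (chromosome 1, 20679010 to 20679082) made up 93.7% of that at 3841 ± 141 CPM. Mir208b in an intron of Myh7, Mir499 in an intron of Myh7b and Mir133b lay at 101 ± 0.15, 81.1 ± 10.6 and 75.3 ± 0.03 CPM. Mir133a-2 had 0 counts in both libraries and Mir1a-1 had 1 in each. Both share long stretches with another copy, 31 and 28 bases, so their levels are uncertain, and they were named after their values were seen. Muscle counts were 11.9-fold below cartilage counts, a log2 ratio of -3.57 ± 0.06 (SD, n = 2), and -9.31 between list medians. Of the counted muscle members 3 of 8 share 22 or more bases with another gene, against 0 of 2 cartilage members. Those 3 may be undercounted, so both values may place muscle too far below cartilage.

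Neuronal genes held 0.0618% ± 0.0009 (SD, n = 2) of counts, with 12 of 17 detected, led by Mir128-1 (167 ± 4.7 CPM), Mir137 (129 ± 21 CPM) and Mir128-2 (114 ± 4.9 CPM). Of the 17 counted members 15 share 22 or more bases with another gene, and Mir124a-1, Mir124a-2, Mir124a-3 and Mir9-2, named after their values were seen, had 0 counts in both libraries. The neuronal share was 0.0168% without genes sharing 18 or more bases and 0.0137% without those sharing 22 or more. The log2 ratio of muscle over neuronal counts was 2.73 ± 0.08 (SD, n = 2), or 6.63-fold. It was 4.92 and 4.95 without genes sharing 18 or more and 22 or more bases, and 1.31 between list medians. Without the most abundant member of each list, Mir206 and Mir128-1, it was -0.80.

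The endothelial gene Mir126a, overlapping an annotated exon of Egfl7 on chromosome 2, held 2.02% ± 0.08 (SD, n = 2) of counts. Blood genes held 0.0747% ± 0.0080 with 6 of 7 detected, among them the myeloid gene Mir223 (318 ± 1.6 CPM), Mir155 (282 ± 81 CPM) and the erythroid pair Mir451a (74.8 ± 0.03 CPM) and Mir144 (50.9 ± 3.1 CPM). The log2 ratio of blood over endothelium was -4.76 ± 0.10 (SD, n = 2). Between list medians it was -8.61. With both strands counted it was -4.13, as Mir142b then gained 409 CPM of antisense reads. Mir142, the blood gene on the other strand, is not counted under its own gene here. Vascular smooth muscle held 0.683% ± 0.057, with Mir143 at 6719 ± 567 CPM and Mir145a at 108 ± 1.4 CPM. Lists of tissues outside the limb held few counts in sum: liver held 0.0197% ± 0.0005, led by Mir192 (83.9 ± 1.4 CPM) and Mir122 (73.7 ± 9.8 CPM). By list median as counted here, liver was not set apart from all limb lists. Its median log2(CPM + 1) was 5.75, against 3.94 for skeletal muscle, 2.63 for neuronal and 5.70 for blood genes. The medians of cartilage, mesenchyme and bone, epithelium, endothelium and vascular smooth muscle were higher. Genes sharing 22 or more bases may be undercounted. They made up 3 of 8 counted skeletal muscle, 15 of 17 neuronal, 2 of 4 liver and 0 of 7 blood members. The blood list also holds Mir142b, with 0 sense counts. The order of these medians may therefore reflect the counting and does not rank the tissues. The heart gene Mir208a lay at 6.78 ± 2.66 CPM, from 29 and 52 counts.

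**Figure D2:**
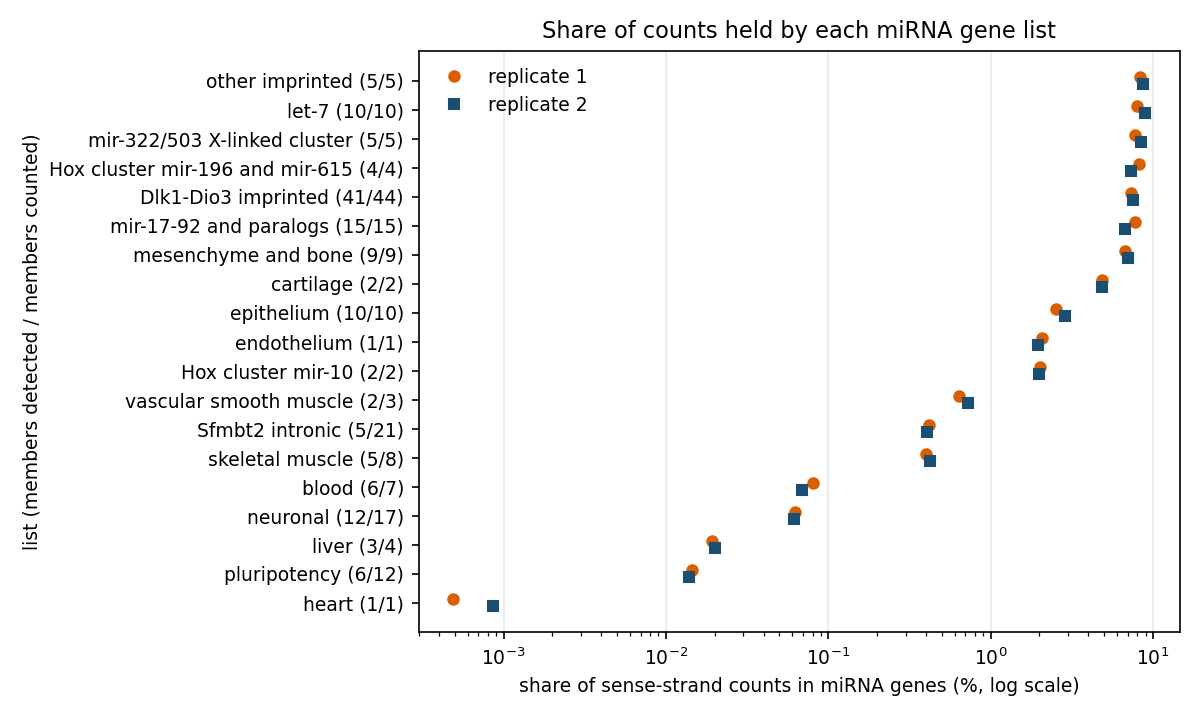
Percent of sense-strand counts in miRNA genes (log scale) held by each of 19 lists, with 1 point per replicate and the number of members detected over those counted. The lists span from 8.49% for other imprinted genes to 0.000678% for heart.

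All 6 list ratios had the same direction in both libraries, but 2 libraries cannot give a two-sided exact p below 0.5, so none was tested. Except for heart (84.6) the medians of the lists lay above percentile 97 of 10000 random lists drawn from all annotated genes. That held for liver and pluripotency too, because most annotated genes were at 0, so the percentile separates the lists little.

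Of the 372 detected miRNA genes, 166 lay in 55 clusters. The Mir322 cluster on the X chromosome (53047997 to 53054349) held 8.10% ± 0.56 (SD, n = 2) of counts, with Mir322, Mir351 (7768 ± 686 CPM), Mir503 (1955 ± 183 CPM) and Mir542 (1342 ± 59.8 CPM). The Mir487b cluster on chromosome 12 (109709060 to 109747960) held 5.35% ± 0.06 across 34 genes, 31 of them detected. The Mir17 cluster on chromosome 14, within Mir17hg, held 5.04% ± 0.63, with Mir17 and Mir20a (11502 ± 1592 CPM) ahead. Levels within a cluster still differed widely. The median absolute log2 difference between next neighbours within 10 kb was 3.60 over 144 pairs, against 4.34 for shuffled partners (95% range 3.58 to 5.15, one-sided permutation test with 100000 resamples, p = 0.0291). This closeness was not past the threshold for neighbours within 1 kb (3.88, permutation p = 0.127) or when both neighbours were detected (2.91, permutation p = 0.149). Pairs that share a gene are not independent, and genes are not replicates.

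The libraries held much the same miRNA genes in much the same order. Across 410 genes Pearson's r of log2(CPM + 1) was 0.996 and Spearman's rho 0.990, values across genes, which are not independent replicates. Genes of at least 100 CPM numbered 190, and their median absolute log2 ratio between libraries was 0.13, with a highest value of 0.73. The biological coefficient of variation was 0.111 over 372 genes (edgeR). A chi-square of 39337.9 on 443 degrees of freedom showed that the libraries differed beyond counting noise, so the tables are not the same counts deposited again. It does not tell separate samples from separate preparations, and the count of 2 replicates rests on the labels.

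In an exact binomial test of 444 genes with Benjamini-Hochberg adjustment, 15 passed the threshold with an absolute log2 ratio of at least 1, 4 higher and 11 lower in replicate 2. Without the minimum ratio, 179 passed. The 15 were scarce genes: 14 had a mean under 10 CPM, such as Mir1960 in an intron of Hadhb (11 and 1 counts in replicates 1 and 2), Mir6946 (10 and 1), Mir6979 (9 and 1), Mir129-1 (3 and 19), Mir1191 (30 and 7) and Mir5130 (21 and 5). Gm24245, Mir669h, Mir3079 and Mir7666 completed the 10 with the largest ratios. The exception was Gm23935, outside those 10 and named after its values were seen, with 171 and 381 counts, a log2 ratio of 1.14 and an adjusted p of 5.03e-18 by the exact test. Gm23935 shares 57 bases with Gm24270, and Gm24245 shares 57 bases with Gm23935. Both are therefore uncertain, and their calls need not be independent. This test compares these libraries and covers counting error only.

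Members of some lists leaned the same way between the libraries by less than the minimum ratio. In the epithelial list 7 of 10 members were higher in replicate 2, with a median log2 ratio of 0.22. Of the 10, 8 passed the adjusted p of the exact binomial test, but none reached the minimum log2 ratio, so no member was called over all genes or adjusted over the list alone. Over all genes 179 of 444 passed, and passing depends on depth: the abundant Mir99a passed at a log2 ratio of -0.02. Mir182, named after its value was seen, went the other way, at -0.23. Of the Mir17 cluster and its paralogs 4 of 15 were higher in replicate 2, with a median of -0.22, and 12 passed the adjusted p. In the Mir322 and Mir503 list 4 of 5 members were higher in replicate 2 (median 0.18) and 5 passed the adjusted p. All 5 detected skeletal muscle genes were higher, Mir133b and Mir208b by very little (median 0.07, 2 past the adjusted p), and 0 of the 4 genes of the Hox list led by Mir196b (median -0.14, 3 past it). Mir19b-2 (46 and 19 counts, named after they were seen) was called in the Mir17 list over all genes and adjusted over the list alone, as was Mir129-1 in the neuronal list. In the remaining lists no member was called either way. Among 10000 lists matched on expression, the epithelial median lay at percentile 100, that of the Mir17 list at 0.01, the Mir322 and Mir503 list at 98.8, skeletal muscle at 83.9 and the Hox list at 7.66, with 17 lists looked at. The Sfmbt2 intronic list lay at 3.21 (median -0.24, with 2 of 5 detected members higher) and let-7 at 93.5. The remaining lists lay between 13.4 and 78.1. Those random lists draw single genes, whereas members of several of these lists share clusters and are not independent draws, so the percentiles can be too extreme.

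**Figure D3:**
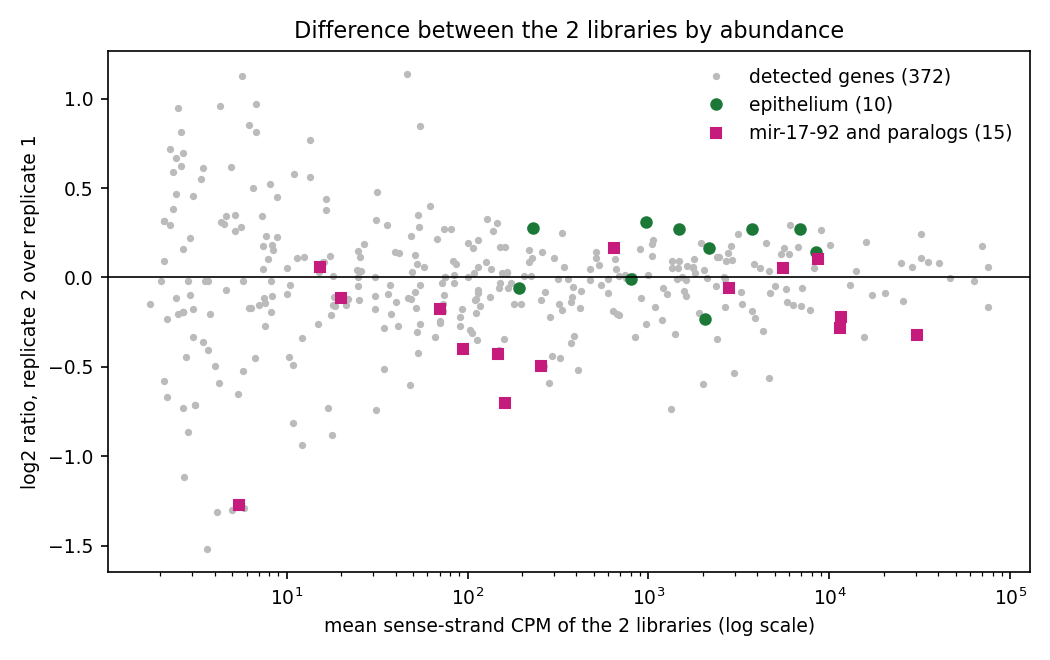
Log2 ratio of replicate 2 over replicate 1 against mean sense-strand CPM (log scale) for the 372 detected genes in grey, with the 10 epithelial genes and the 15 genes of the Mir17 cluster and its paralogs marked. The epithelial genes have a median of 0.22 and the Mir17 list a median of -0.22, while scarce genes scatter most.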

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

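The tests in this part were chosen after the result was seen. Reads on the antisense strand of annotated miRNA genes lay outside the main measurement and far above the limit that a count of 0 allows. They reached a mean of 8865 CPM over Gm25301, opposite Mir378a, 8061 CPM over Gm24321, opposite Mir409, and 5415 CPM over Gm25927, opposite Mirlet7e. Over Gm25252, opposite Mir376a, they lay at 3829 CPM, over Gm24083, opposite Mir191, at 2226 CPM, over Mir299b, opposite Mir299a, at 2029 CPM, and over Gm25750, opposite Mir380, at 1654 CPM. Mir497b, opposite Mir497, had 589 CPM, Mir142b, opposite Mir142, 409 CPM, Mir3074-1, opposite Mir24-1, 83.7 CPM, and Gm24111, opposite Mirlet7f-1, 50.1 CPM.

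Leakage of strand in the library is argued against by genes with 10000 or more sense reads in each library: over 76 such genes the median antisense share was 0%, with a highest value of 0.176% for Mir708. Reads of a miRNA gene on the other strand are a candidate source. Of the genes with 100 or more antisense reads in each library, 11 of 11 overlap such a gene. Among the 1894 genes matched to the annotation, 32 do. No partner of these 32 was counted under its own gene here, so the uncounted partners of the 11 add no evidence. The 11 genes held 99.9% of antisense gene reads in each library. By level the reads over Gm25301 would rank at 24 among the sense values of this limb profile, so Mir378a, Mir409 and Mirlet7e may be abundant genes that the sense counts leave out. No biological explanation was tested, as the design has 1 group.

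Multimapping reads made up 30.1% of all reads (mean of the libraries), and uniquely mapped reads on the sense strand of no gene 4.36%. Both lie outside the main measurement and are given as values, with no test.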

How the results depend on the processing

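Detected genes, calls between libraries and the coefficient of variation stayed close to their values under most settings, with these exceptions, and the cause was not tested except where the setting itself shows it. Lowering the minimum to 1 count gave 570 detected genes. The share of the top 10 genes was 23.8% of all reads and 48.3% with both strands counted. Pearson's r was 0.992 and 0.998 at pseudocounts of 0.1 and 10 CPM, and 0.997 both without a filter and at 50 or more counts. DESeq2's dispersions gave a coefficient of variation of 0.140. Calls numbered 5 at 50 or more counts in both libraries together, which tests fewer genes, and 179 with no minimum ratio, a setting added after the data were seen. Neighbours within 1 kb differed by 3.88 and detected pairs by 2.91, neither past the threshold (permutation p = 0.127 and 0.149); the other settings ranged from 2.82 to 3.62 and from p = 0.00436 to 0.0441. Log2 ratios of lists moved too. Without genes sharing 18 or more bases, muscle over neuronal was 4.92, mesenchyme and bone over epithelium 0.091 and let-7 over pluripotency 7.31. Without those sharing 22 or more, muscle over neuronal was 4.95. Between list medians, muscle over neuronal was 1.31, muscle over cartilage -9.31, mesenchyme and bone over epithelium -2.57, let-7 over pluripotency 8.75, the Hox ratio 2.88 and blood over endothelium -8.61. Without the most abundant member of each list, muscle over neuronal was -0.80, muscle over cartilage -2.96, mesenchyme and bone over epithelium 0.87, let-7 over pluripotency 8.93 and the Hox ratio 1.19; blood over endothelium has no such value, as the endothelial list has 1 counted member. With both strands counted it was -4.13. The settings with 22 bases and without the most abundant member were also added after the data were seen. Each library alone left all 19 list shares within 1 SD, by construction of an SD over 2 libraries. List shares moved by more than 1 SD for 17 lists without genes sharing 18 bases, 8 without genes sharing 22, 14 without the most abundant gene and 9 with both strands. Each setting also changes the total, which alone moves lists that lose no member. Cartilage kept both members without genes sharing 18 bases, yet went from 4.86% to 6.09%, against an SD of 0.006. These numbers of lists therefore do not measure dependence on shared sequence. Correlation, calls and the coefficient of variation need both libraries, so neither was left out there. No paired analysis was possible because the series has 1 group. Depth limits the scarce genes, where 14 of 15 calls lay.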

Other observations

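By chromosome, the highest share was that of chromosome 6 with 15.8% ± 0.4 (SD, n = 2) from 12 detected genes. Nearly all of it came from Mir196b and Mir335, at 75238 and 75047 CPM. The X chromosome held 10.7% ± 0.7 from 42, chromosome 12 held 8.73% ± 0.11 from 57 and chromosome 2 held 8.30% ± 0.04 from 29. Chromosome 3 held 0.212% ± 0.007 from 13. Members of 1 cluster often differed many-fold, in pairs named here after their values were seen. Mir99a stood at 62771 CPM beside Mirlet7c-1 at 93.5 ± 8.1 CPM, Mir100 at 17236 CPM beside Mirlet7a-2 at 118 ± 9.2 CPM, and Mir30e at 15602 CPM beside Mir30c-1 at 57.7 ± 1.6 CPM, where each lower member shares 22 or more bases with a copy elsewhere. Mir99b stood at 25670 CPM beside Mir125a at 3872 ± 426 CPM, and Mir23a at 15886 CPM beside Mir27a at 224 ± 0.8 CPM, although Mir125a shares no such stretch and Mir27a shares 20 bases. The X-linked Mir532 cluster held 0.690% ± 0.016 with 5 of 5 genes detected.

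The tests in the paragraphs that follow were chosen after the results were seen, and no biological explanation was tested, since the design has 1 group. In addition, 3 tests were specified again after a first run. Leaving out the members of the Sfmbt2 list alone had changed no value, so whole clusters holding them were left out instead. A test of sequencing depth for the epithelial genes was replaced by one of gene-to-gene variation, because CPM scaling already removes a common factor per library. A test of GC content that read the same percentile of the epithelial list again was replaced by one on genes outside the list.

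Low counts of genes with copies, such as Mirlet7c-1, Mir133a-2 and Mir124a-1, are a first pattern. In 18 clusters holding both kinds, genes sharing 22 or more bases lay on average -2.95 (SE 1.16) on the log2 scale relative to single-copy members, lower in 15 of 18 clusters (one-sided permutation p = 0.0115), so loss of reads shared between copies is a candidate explanation. The Sfmbt2 cluster alone is argued against, as the mean was -3.09 without it (permutation p = 0.0120). Whether any similarity to another hairpin would do the same cannot be told apart from this: genes sharing 18 to 21 bases gave -1.07 (SE 1.55) over 7 clusters (permutation p = 0.234), too few to decide. The low values of Mirlet7c-1 and of neuronal genes with copies may therefore be underestimates.

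A second pattern is the higher level of epithelial genes in replicate 2, with Mir429, Mir200c and Mir205 at log2 ratios of 0.27 each, Mir203 at 0.14 and Mir183 at 0.17, while Mir182 at -0.23, Mir200a at -0.06 and Mir96 at -0.007 did not share it (Mir200c and these 3 named after their values were seen). Other lists differed too: relative to replicate 1, summed counts differed by 12.9% for epithelium, 11.9% for let-7 and -13.3% for the Mir17 list, and, resting mainly on a single gene, by 10.3% for the Mir322 and Mir503 list (85.9% Mir322), -10.9% for the Hox list (96.7% Mir196b), 12.5% for vascular smooth muscle (98.4% Mir143), -14.1% for blood (Mir155, 2008 and 1349 counts, with 3 of 6 members higher) and 77.0% for heart (Mir208a, 29 and 52 counts). Hairpin GC content as the whole cause is argued against, as genes outside the list with the nearest GC gave a median of -0.015 (95% bootstrap range -0.09 to 0.06) against the observed 0.22, and GC and log2 ratio had a Spearman's rho of 0.077 across 372 genes. Gene-to-gene variation between the libraries stays open, since the percentile of 100 over 5 epithelial loci repeats the measure that picked out the list. A larger share of surface ectoderm in replicate 2 may add to the pattern but cannot be told apart from other causes, library preparation among them: the spread of the members lay at percentile 48.2 of matched lists, and lists not fixed as epithelial, such as let-7 and the Mir17 list, differed between the libraries as well.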
